A study of Homo sapiens with 12 samples.

How the data were processed

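RNA sequencing was carried out on HEK293T cells, a human embryonic kidney line that carries the SV40 large T antigen. Per the labels, cells were kept for 24 h with or without ferric ammonium citrate (FAC, a soluble iron salt) at 0.1 mg/ml, and then for a further 24 h with or without bafilomycin A1 (BafA1, an inhibitor of the V-ATPase that acidifies lysosomes) at 10 nM. This gave 4 groups of 3 libraries: control, BafA1, FAC and FAC+BafA1. Libraries were made with a stranded mRNA kit, per the labels' protocols, which select polyadenylated RNA. The labels number the replicates but do not say that they came from separate cultures, so the p-values measure the spread between these samples.

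The deposited table gives FPKM (fragment counts scaled to transcript length and library depth) for 56340 gene entries in 12 columns, as made by the authors and rounded to 2 decimals. Per the submitters' processing notes, STAR, RSEM and the genome build GRCh38 were used. Their versions, the annotation release, any filters and whether counting used the strand are not given in the sources used here. Of the 56340 entries, 3 repeated another gene ID with 0 in every library and were dropped. Gene symbols were taken from the table and from a reference list of gene names that matched 56104 of 56337 distinct IDs, with 13 symbol fields made of digits only replaced through the ID. Gene positions and types came from GENCODE release 44 on GRCh38, which need not be the release the authors used.

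FPKM are not counts, so no count model was run. Depth was estimated from the low values, which fall on steps of 1 fragment: genes with 1 listed transcript of 700 to 2000 bases and an FPKM under 0.5 were used, with an assumed fragment length of 150 bases. The depth that brought these values closest, on average, to whole numbers of fragments was 35 to 39.5 M fragments (M, 10 to the power of 6) per library. The share of values within 0.2 of a whole number was 65.2% to 69.4% in the 6 libraries without FAC and 83.7% to 88.6% in the 6 with FAC. These depths are estimates, and no count was recovered from them.

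Values were transformed to log2(FPKM + 1) without further scaling. Genes with a mean of at least 1 FPKM over the 12 libraries were kept, which left 13682 genes, of which 11569 are protein coding in the reference annotation. The groups were compared with limma 3.58.1 in R 4.3.3, with a mean per group, all 12 libraries in 1 fit and an intensity trend in the prior variance. Within each of 6 comparisons, p-values were adjusted by the Benjamini-Hochberg method and genes with an adjusted p under 0.05 were called. The comparisons were BafA1 with control, FAC with control, FAC+BafA1 with BafA1, FAC+BafA1 with FAC, FAC+BafA1 with control, and the interaction, which is the BafA1 change with FAC minus the BafA1 change without FAC. Log2 changes are on the log2(FPKM + 1) scale, which understates the change of low genes; folds are ratios of mean FPKM. Errors of FPKM are SDs over 3 libraries and errors of log2 changes are limma standard errors.

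The design, the gene lists, the rule for naming genes and most alternatives were fixed before the data were examined. Of 26 lists, 23 had enough members above the expression minimum: iron handling, HIF targets, glycolysis, cholesterol synthesis and uptake, fatty acid synthesis, V-ATPase subunits, lysosomal hydrolases and membrane proteins, autophagy, ATF4 amino acid response, ER unfolded protein response, nuclear-encoded respiratory chain, mitochondrially encoded genes, iron-sulfur cluster and heme assembly, DNA replication, mitosis, p53 targets, NRF2 targets, metallothionein and zinc response, interferon and NF-kB response, cytosolic ribosomal proteins, immediate early genes, heat shock and replication-dependent histones. The other 3 were markers of keratinocytes or HeLa cells, blood cells and fibroblasts. Some lists share members, so their results are not fully separate. STC2 is in the HIF and ATF4 lists, HK2 in HIF and glycolysis, and SLC7A11 in ATF4 and NRF2. HMOX1 is in iron handling and NRF2, and ME1 in fatty acid synthesis and NRF2. Lists were tested with limma's camera, which compares a list with all other genes, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over 23 lists and 6 comparisons; an estimated correlation and the fry test were run as alternatives. Member counts are given over all genes tested, and with the adjustment over the list alone where the counts differ.

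Genes were named by a fixed rule. For the 4 main comparisons (BafA1 with control, FAC with control, FAC+BafA1 with BafA1, interaction) it took the 5 largest increases and the 5 largest decreases among called genes with a regular symbol, and, for comparisons of a pair of groups, no overlap between replicate values. It added up to 4 called members per described list with the smallest adjusted p (1 member where no member was called). Named in every comparison were TFRC, SLC11A2, FTH1, FTL, CA9, NDRG1, VEGFA, HMGCS1, SQSTM1 and ASNS. Some genes that the rule takes are not reported here. For the other comparisons it took those genes and the 3 largest changes each way. A name filter that had left out FOS by error was corrected after the results were seen. Genes outside the rule are said to have been chosen after their values were seen.

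The tests were checked on simulated data, in which 200 of 13682 genes were given known changes in 5 draws. For BafA1 with control, 82.1%, 95.5% and 98.2% of genes changed by 0.5, 1 and 2 log2 units were recovered, and 4.47% of calls were false. For the interaction these shares were 65.7%, 91.0% and 96.7%, with 4.63% of calls false. In BafA1 with control, the list test recovered the 1 shifted list among 23. The noise was drawn independently for each gene and library. These checks therefore do not cover genes that vary together, a shift of a whole library or data in which most genes change.

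Alternatives tried were a pseudocount of 0.1, no filter or a minimum mean of 5 FPKM, median-of-ratios scaling, quantile normalization, no intensity trend, array weights, the replicate number as a block, each library left out in turn, only the 2 groups compared, and a minimum log2 change of 1. After the data were seen, coding genes that overlap no other annotated gene and have no named pseudogene (isolated coding genes, 2634 of those tested) and genes with a mean of at least 1 FPKM in the libraries both with and without FAC were added as alternatives. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, with pandas 2.3.3. Sequencing reads were not used here.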

Results

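Transcript levels were measured by RNA sequencing of polyadenylated RNA in HEK293T cells in 4 groups of 3 libraries: control cells, cells given BafA1, cells given FAC, and cells given FAC and then BafA1. The estimated depth was 37.2 ± 1.88 M fragments per library in control, 35.7 ± 0.58 in BafA1, 38.3 ± 1.01 in FAC and 36.9 ± 0.52 in FAC+BafA1 (SD, n = 3). Each library had 13244 to 13597 genes at 1 FPKM or more. Mitochondrially encoded genes held 2.85 ± 0.35% of all FPKM in BafA1, 1.91 ± 0.33% in control, 1.70 ± 0.19% in FAC and 1.97 ± 0.26% in FAC+BafA1. Across genes, which are not independent replicates, the correlation of log2 values was 0.993 to 0.995 within groups. It was 0.959 to 0.991 between groups that were alike in FAC and 0.873 to 0.907 between groups that differed in FAC.

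The libraries with and without FAC also differed in how gene entries were filled. A set of 627 genes was listed at 0 in all 6 libraries of one side and at 1 FPKM or more in all 6 of the other: 304 were at 0 without FAC and 323 at 0 with FAC. Of these, 595 were non-coding and 31 of the 32 coding genes overlapped another gene. With the groups parted by BafA1, or with control and FAC+BafA1 set against BafA1 and FAC, 0 genes showed this. The 2 comparisons of BafA1 within one side set each gene entry against libraries filled in the same way; the 3 comparisons across FAC do not. The interaction sets a change measured with one filling of the entries against a change measured with the other.

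The comparison of BafA1 with control asked which transcripts change when lysosomal acidification is blocked without added iron. TFRC, which encodes the receptor that brings transferrin-bound iron into cells, rose from 58.3 ± 0.991 to 130.2 ± 3.05 FPKM (SD, n = 3), 2.23-fold, with every BafA1 library above every control library. Genes of the ATF4 amino acid response, which restore amino acid supply under stress, rose as a group, with a median log2 change of 1.55 over 37 genes. ASNS, which makes asparagine, rose 2.93-fold from 144 ± 6.17 to 423 ± 4.32 FPKM. The hypoxia-responsive genes NDRG1, a growth and differentiation gene that iron chelators induce, and VEGFA, an angiogenic growth factor, rose 4.05-fold and 3.44-fold. HSPA1B, an inducible chaperone gene, fell from 553 ± 42.4 to 62.2 ± 2.01 FPKM.

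The limma fit called 9180 of 13682 genes at an adjusted p under 0.05, 4039 higher and 5141 lower with BafA1. The larger number of lower genes was not found with median-of-ratios scaling, where 50.4% of calls were higher, and was smaller under quantile normalization (47.3% higher). Of the 9180, 680 changed by at least 1 log2 unit (386 higher, 294 lower). The log2 change was 1.15 ± 0.06 for TFRC (SE, adjusted p = 1.04e-08) and 1.55 ± 0.03 for ASNS (adjusted p = 4.51e-12). It was 1.96 ± 0.07 for NDRG1 (adjusted p = 3.10e-10) and 1.70 ± 0.09 for VEGFA (adjusted p = 8.82e-09). SQSTM1, which encodes the autophagy receptor p62, rose 1.57-fold (log2 0.64 ± 0.03, adjusted p = 1.04e-08). SLC11A2, the divalent metal transporter, rose by 0.22 ± 0.06 (adjusted p = 0.0062), and FTL, the ferritin light chain, by 0.25 ± 0.04 (adjusted p = 0.000123). FTH1, the ferritin heavy chain, was -0.14 (adjusted p = 0.00508), a call that was lost with median-of-ratios scaling (adjusted p = 0.102) and with quantile normalization (adjusted p = 0.996). The ferritin genes have processed pseudogenes, so their read assignment is uncertain. HMGCS1, which catalyses an early step of cholesterol synthesis, was at 51.3 ± 0.860 FPKM in control and 53.04 ± 1.44 in BafA1 (log2 0.05 ± 0.03, adjusted p = 0.188), and was called higher only under median-of-ratios scaling (adjusted p = 0.00876). CA9, a hypoxia-induced carbonic anhydrase, was at 0 to 0.05 FPKM in every library and was not tested.

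The 5 largest increases that the naming rule took after BafA1 were in EGR1, ATF3, FOS, C11orf96 and ARC. EGR1, an immediate early transcription factor, rose from 0.487 ± 0.0153 to 188 ± 21.1 FPKM (log2 6.98 ± 0.10, adjusted p = 3.47e-13). ATF3, a stress-induced transcription factor, rose from 19.8 ± 1.52 to 539 ± 22.2 FPKM, 27.2-fold. FOS, a subunit of the transcription factor AP-1, rose from 0.307 ± 0.0473 to 30.8 ± 2.86 FPKM (log2 4.60 ± 0.12, adjusted p = 3.21e-11). C11orf96 rose by 4.39 ± 0.09 and ARC, a synaptic immediate early gene, by 4.23 ± 0.15 log2 units (adjusted p = 5.46e-12 and 3.19e-10). The 5 largest decreases that the rule took were in HSPA1B (log2 -3.13 ± 0.06, adjusted p = 2.92e-12), its near-identical neighbour HSPA1A (log2 -2.67 ± 0.13), LRRC20, HOXA13 and MIR3661. The split of reads between HSPA1B and HSPA1A is uncertain. LRRC20, a leucine-rich repeat gene, was at -1.90, HOXA13, a limb and genital patterning factor, at -1.87, and MIR3661, a microRNA entry within a host gene and so uncertain, at -2.15 log2 units (adjusted p = 6.95e-11, 7.87e-09 and 0.00339).

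Among the gene lists, 35 of 37 ATF4 genes were higher (camera adjusted p = 5.10e-21, and 0.000609 with an estimated correlation). CTH, which makes cysteine, rose from 15.9 ± 0.928 to 135 ± 2.64 FPKM. Of 20 genes of the ER unfolded protein response, 16 were higher and 2 lower, with a median of 0.97 (adjusted p = 5.35e-09, and 0.00253 with an estimated correlation). HSPA5, the main ER chaperone, rose from 183 ± 2.88 to 607 ± 25.8 FPKM, and XBP1, a transcription factor of that response, from 87.3 ± 0.520 to 292 ± 3.73. Of 44 HIF targets, 28 were higher and 10 lower, with a median of 0.45 (adjusted p = 2.99e-05, and 0.01 with an estimated correlation). HK2, a hexokinase, rose by 1.72 ± 0.04 and BHLHE40, a transcriptional repressor, by 2.13 ± 0.05 log2 units. Of 12 immediate early genes, 11 were higher (median 1.83, adjusted p = 6.09e-09, and 0.0242 with an estimated correlation).

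Lower lists after BafA1 included heat shock, cholesterol synthesis and uptake, and iron-sulfur cluster and heme assembly. Of 11 heat shock genes, 10 were lower, with a median of -1.16 (adjusted p = 1.07e-05, and 0.0188 with an estimated correlation). HSPA8, the constitutive cytosolic chaperone, fell by 1.59 ± 0.02 log2 units. Of 26 cholesterol genes, 19 were lower and 2 higher (median -0.34, adjusted p = 0.000425, and 0.0324 with an estimated correlation). Among the lower ones were SQLE, which oxidises squalene (log2 -0.92 ± 0.03), and NSDHL, a sterol dehydrogenase (log2 -0.89 ± 0.04). Of 31 iron-sulfur cluster and heme genes, 21 were lower and 3 higher, or 21 and 4 adjusted over the list alone (median -0.29, adjusted p = 0.0147, and 0.0473 with an estimated correlation). In that list NFS1, the cysteine desulfurase, was at -0.87 and ALAS1, which starts heme synthesis, at 0.96 log2 units.

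Several lists passed camera with the preset correlation but not with an estimated one. Of 33 nuclear-encoded respiratory chain genes 30 were lower, with a median of -0.41 (adjusted p = 2.32e-08, and 0.0626 with an estimated correlation). ATP5MC1, a subunit of ATP synthase, was at -1.45 log2 units. The lysosomal hydrolases and membrane proteins had 23 of 40 lower and 6 higher, or 24 and 6 adjusted over the list alone (median -0.22, adjusted p = 0.0257, and 0.133 with an estimated correlation). The autophagy list had 12 of 31 higher and 4 lower (median 0.10, adjusted p = 0.024, and 0.0615 with an estimated correlation), and was also lost at a mean of at least 5 FPKM (adjusted p = 0.0669). The mitochondrially encoded genes had 8 of 13 higher (median 0.40, adjusted p = 0.016, and 0.617 with an estimated correlation). The metallothionein and zinc response had 5 of 6 lower (median -0.75, adjusted p = 0.0289, and 0.0915 with an estimated correlation). The cytosolic ribosomal proteins had 14 of 25 lower (median -0.13, adjusted p = 0.0254, and 0.641 with an estimated correlation). That call was also lost with median-of-ratios scaling (adjusted p = 0.192), without control replicate 2 (adjusted p = 0.0551) and without BafA1 replicate 3 (adjusted p = 0.0521), and under quantile normalization its median was 0. It was lost as well with no intensity trend (adjusted p = 0.0543) and with the 2 groups fitted alone (adjusted p = 0.0604).

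The other lists did not pass camera as groups, although many of their members were called. Iron handling had 8 of 23 genes higher and 11 lower; its median was -0.09 and its mean -0.09, while the camera direction was up (adjusted p = 0.932). In it NCOA4, the receptor for ferritin breakdown, rose by 0.54 ± 0.03 and SLC39A14, a zinc and iron importer, by 0.56 ± 0.03 log2 units. HMOX1, which degrades heme, fell from 21.2 ± 1.42 to 7.97 ± 0.140 FPKM (adjusted p = 1.04e-08). The medians and camera adjusted p were -0.01 and 0.904 for 16 glycolysis genes, -0.31 and 0.43 for 14 fatty acid synthesis genes, -0.12 and 0.375 for 19 V-ATPase subunits and 0.01 and 0.611 for 39 DNA replication genes. They were 0.10 and 0.185 for 27 mitosis genes, 0.15 and 0.233 for 23 p53 targets, 0.25 and 0.227 for 12 interferon and NF-kB response genes and -0.10 and 0.997 for 4 replication-dependent histones. The 18 NRF2 targets had a median of -0.47 (adjusted p = 0.0602), but passed without BafA1 replicate 2 (adjusted p = 0.0483) and with no filter on low values (adjusted p = 0.00474). Of the markers of other cell types, 0 of 8 for keratinocytes or HeLa cells, 2 of 13 for blood cells and 1 of 8 for fibroblasts reached the expression minimum.

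**Figure D1:**
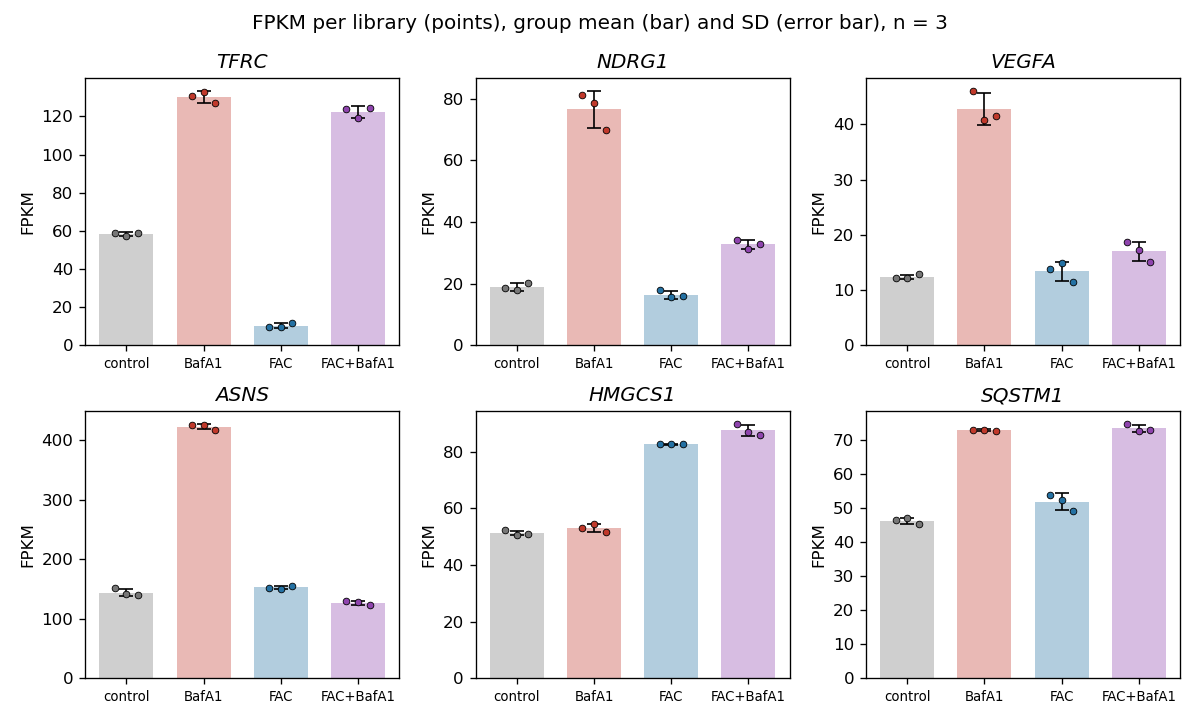
FPKM of TFRC, NDRG1, VEGFA, ASNS, HMGCS1 and SQSTM1 in each library (points) of the 4 groups, with bars at the mean and error bars of 1 SD (n = 3). TFRC was at 58.3 FPKM in control, 130.2 in BafA1, 10.2 in FAC and 122 in FAC+BafA1.

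The comparison of FAC+BafA1 with FAC asked what BafA1 did once iron had been supplied. TFRC rose from 10.2 ± 1.29 to 122 ± 3.03 FPKM (SD, n = 3), 11.9-fold, the largest log2 increase that the naming rule took (3.46 ± 0.06, SE; limma adjusted p = 1.71e-11). EGR1 rose from 0.537 ± 0.102 to 13.8 ± 1.89 FPKM and TNFRSF12A, the receptor for the cytokine TWEAK, by 2.46 ± 0.09 log2 units (adjusted p = 1.13e-08). HMOX1 fell from 40.3 ± 3.81 to 11.1 ± 0.723 FPKM (adjusted p = 1.58e-08) and MAP2K6, a stress kinase, from 12.6 ± 0.757 to 5.34 ± 0.472 FPKM (adjusted p = 1.40e-05). The fit called 2634 genes, 1336 higher and 1298 lower, of which 53 changed by at least 1 log2 unit (46 higher, 7 lower).

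NDRG1 rose by 0.95 ± 0.07 (adjusted p = 2.73e-06), SQSTM1 by 0.50 ± 0.03 (adjusted p = 2.00e-06) and SLC11A2 by 0.52 ± 0.06 (adjusted p = 0.000144). FTH1 rose by 0.25 ± 0.04 (adjusted p = 0.000795) and FTL by 0.21 ± 0.04 log2 units (adjusted p = 0.00347). ASNS was at -0.27 ± 0.03 (adjusted p = 0.000163), that is lower, where it had risen without FAC. VEGFA was at 0.33 ± 0.09 (adjusted p = 0.0249), a call lost without FAC replicate 3 (adjusted p = 0.0765), FAC+BafA1 replicate 1 (adjusted p = 0.0974), FAC+BafA1 replicate 2 (adjusted p = 0.0741) or with the 2 groups fitted alone (adjusted p = 0.124). HMGCS1 (0.08, adjusted p = 0.0723) did not pass the threshold, although it did under quantile normalization (adjusted p = 0.0305) and with the 2 groups fitted alone (adjusted p = 0.0481). A Y RNA entry (ENSG00000199476) was also among the largest decreases and was listed at 0 in FAC+BafA1; it is one of many near-identical copies and its value is uncertain.

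With FAC, the immediate early genes were higher after BafA1 in 10 of 12 genes (median 0.87, camera adjusted p = 1.12e-13, and 0.0143 with an estimated correlation). HIF targets had 18 of 44 higher and 4 lower, or 25 and 5 adjusted over the list alone (median 0.17, adjusted p = 0.000233, and 0.0143 with an estimated correlation). Lysosomal genes had 12 of 40 higher, or 15 adjusted over the list alone (median 0.11, adjusted p = 7.68e-05, and 0.0252 with an estimated correlation), against 6 without FAC. Autophagy genes had 9 of 31 higher, or 10 adjusted over the list alone (median 0.08, adjusted p = 0.000246, and 0.0162 with an estimated correlation). Heat shock genes had 8 of 11 lower, or 9 adjusted over the list alone (median -0.16, adjusted p = 4.39e-06, and 0.0175 with an estimated correlation). Respiratory chain genes had 16 of 33 lower, or 17 adjusted over the list alone (median -0.11, adjusted p = 2.22e-07, and 0.0769 with an estimated correlation). The ATF4 genes went both ways, with 10 of 37 higher and 7 lower, or 11 and 10 adjusted over the list alone, and their median of -0.04 and mean of 0.10 differed in sign (adjusted p = 0.932). The ER unfolded protein response had a median of 0.02 (adjusted p = 0.218), and passed under quantile normalization (adjusted p = 0.0142); cholesterol genes had a median of -0.02 (adjusted p = 0.353). NRF2 targets were lower in 7 of 18, or 8 adjusted over the list alone (median -0.08, adjusted p = 0.000543, and 0.0193 with an estimated correlation), and iron-sulfur cluster and heme genes in 7 of 31, or 10 (median -0.07, adjusted p = 0.0147, and 0.0473 with an estimated correlation). V-ATPase subunits (median 0.09, adjusted p = 0.00733 and 0.0942) and mitochondrially encoded genes (median 0.22, adjusted p = 0.0473 and 0.653) passed with the preset correlation but not with an estimated one. The mitochondrial call depended on single libraries: the median was 0.12 without FAC+BafA1 replicate 1 (adjusted p = 0.266) and 0.13 without FAC replicate 1 (adjusted p = 0.301). It was also lost without FAC+BafA1 replicate 2 (0.0843), control replicate 2 (0.0545) or BafA1 replicate 1 (0.052), with no trend (0.068), a pseudocount of 0.1 (0.0514), a mean of at least 5 FPKM (0.0514) and a replicate block (0.0502).

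The interaction asked whether iron changed the response to BafA1, with each response measured within libraries alike in FAC. Of the 9180 genes called for BafA1 without FAC, 6440 (70.2%) changed less with FAC by the limma interaction test, 23 changed more and 2717 were not called different. With no filter on low values, the share that changed less was 60.8%. The median ratio of the change with FAC to the change without was 0.175. Among the 680 genes that had changed by at least 1 log2 unit, 648 (95.3%) changed less, with a median ratio of 0.206. Genes that turned round also count as changed less, and 196 of the 9180 were called in the opposite direction with FAC. Selection on the change without FAC favours this outcome. Chosen the other way, of 2634 genes called for BafA1 with FAC, 1325 (50.3%) changed more without FAC and 444 (16.9%) less. Their median ratio of the change without FAC to that with FAC was 1.76. In 20 simulated datasets with the same change on both sides, at most 0.0137% of BafA1 calls were lessened and the lowest median ratio was 0.946. Their noise was drawn independently for each gene and library. They therefore address the noise of single genes only, and no shift of a whole library or difference in the range of changes. In all, 6850 genes had a called interaction, 4032 positive and 2818 negative. The excess of positive ones (58.9%) was not found with median-of-ratios scaling (49.3%) and was smaller under quantile normalization (52.7%). Of the 6850, 365 were at least 1 log2 unit in size (134 positive, 231 negative).

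The ATF4 and ER unfolded protein responses lost most of their size with FAC. Of 35 ATF4 genes called for BafA1, 35 changed less, with a median ratio of -0.03. ASNS was at 153 ± 2.29 FPKM in FAC and 127 ± 3.20 in FAC+BafA1 (interaction -1.81 ± 0.05, adjusted p = 1.93e-10). CTH was at 17.7 ± 0.479 and 21.5 ± 0.536 (interaction -2.74 ± 0.06, adjusted p = 1.62e-10). For the ER unfolded protein response 16 of 18 changed less, with a ratio of 0.10. HSPA5 was at 185 ± 2.62 FPKM in FAC and 185 ± 2.88 in FAC+BafA1 (interaction -1.72 ± 0.04, adjusted p = 1.93e-10). For HIF targets 26 of 38 changed less, with a ratio of 0.31. The interaction was -1.01 ± 0.10 for NDRG1 (adjusted p = 6.37e-06) and -1.37 ± 0.13 for VEGFA (adjusted p = 4.15e-06). Of the immediate early genes 11 of 11 changed less, with a ratio of 0.46, and EGR1 still reached 13.8 ± 1.89 FPKM. No test set that ratio against those of the HIF and ER lists. The camera adjusted p of these 4 lists in the interaction were 1.98e-30, 1.12e-13, 8.06e-05 and 7.15e-09, and 0.000402, 0.000924, 0.0117 and 0.0242 with an estimated correlation.

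Decreases were smaller with FAC as well. All 10 heat shock genes called for BafA1 changed less (ratio 0.21), and HSPA1B was at 661 ± 37.7 FPKM in FAC and 363 ± 21.1 in FAC+BafA1 (interaction 2.27 ± 0.08, adjusted p = 3.84e-09). Of 21 cholesterol genes called for BafA1, 19 lower and 2 higher, 18 changed less (ratio 0.22), with an interaction of 0.65 ± 0.05 for SQLE (adjusted p = 6.22e-07), while HMGCS1 was at 0.04 (adjusted p = 0.5). Of 29 lysosomal genes called for BafA1, 23 lower and 6 higher, 24 changed less and 1 more (ratio -0.02). These 2 tallies thus hold increases as well as decreases. The camera adjusted p in the interaction was 1.36e-06 for heat shock, 1.62e-05 for cholesterol and 1.07e-05 for lysosomal genes, and 0.0162, 0.0175 and 0.0188 with an estimated correlation. The respiratory chain had 26 of 33 genes with a positive interaction (adjusted p = 8.37e-07, and 0.087 with an estimated correlation). Iron-sulfur cluster and heme assembly had a median interaction of 0.24 (adjusted p = 0.04, and 0.0808 with an estimated correlation). That call was also lost with median-of-ratios scaling (adjusted p = 0.0616), without BafA1 replicate 3 (adjusted p = 0.0521), without FAC+BafA1 replicate 3 (adjusted p = 0.0536) and at a mean of at least 5 FPKM (adjusted p = 0.0563).

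TFRC went the other way: its BafA1 change was 1.15 log2 units without FAC and 3.46 with FAC (interaction 2.32 ± 0.09, adjusted p = 4.02e-09). FTH1 had an interaction of 0.38 ± 0.05 (adjusted p = 7.85e-05). SLC11A2 had 0.29 ± 0.09 (adjusted p = 0.0137), a call lost with median-of-ratios scaling (adjusted p = 0.0574). FTL had -0.04 ± 0.06 (adjusted p = 0.574), and was called only under quantile normalization (adjusted p = 0.00595). SQSTM1 had -0.15 ± 0.05 (adjusted p = 0.0252), a call lost without control replicate 3, FAC replicate 1, FAC replicate 2, FAC+BafA1 replicate 2 or FAC+BafA1 replicate 3 (adjusted p from 0.0527 to 0.061). Across genes, which are not independent replicates, the correlation of the BafA1 changes with and without FAC was 0.526, and 0.651 over isolated coding genes.

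**Figure D2:**
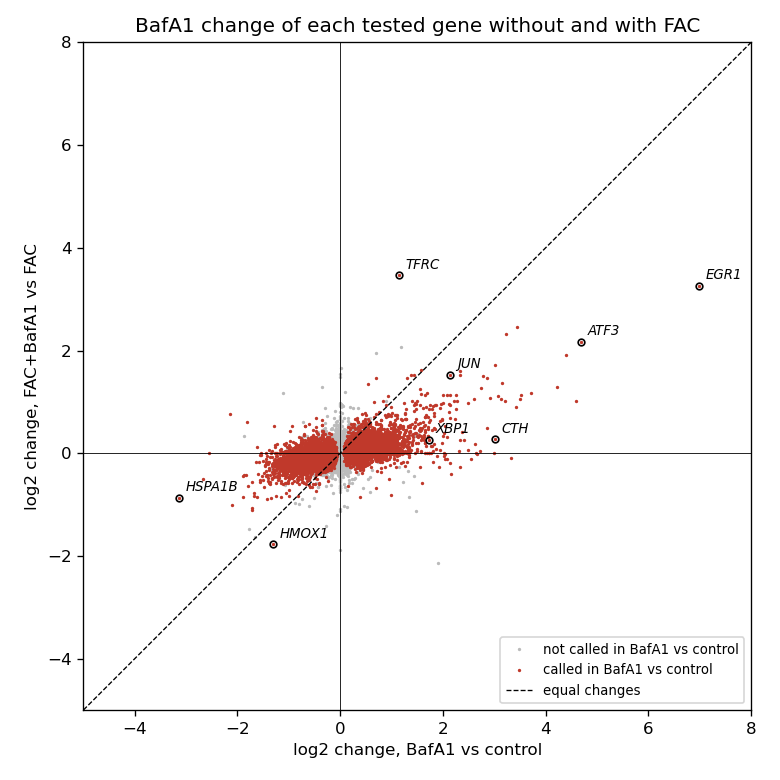
Log2 change of each tested gene after BafA1 without FAC (x axis) and with FAC (y axis), with genes called in BafA1 against control in red and a dashed line where the changes are equal. EGR1 lies at 6.98 and 3.26, and TFRC, which lies above the dashed line, at 1.15 and 3.46.

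**Figure D3:**
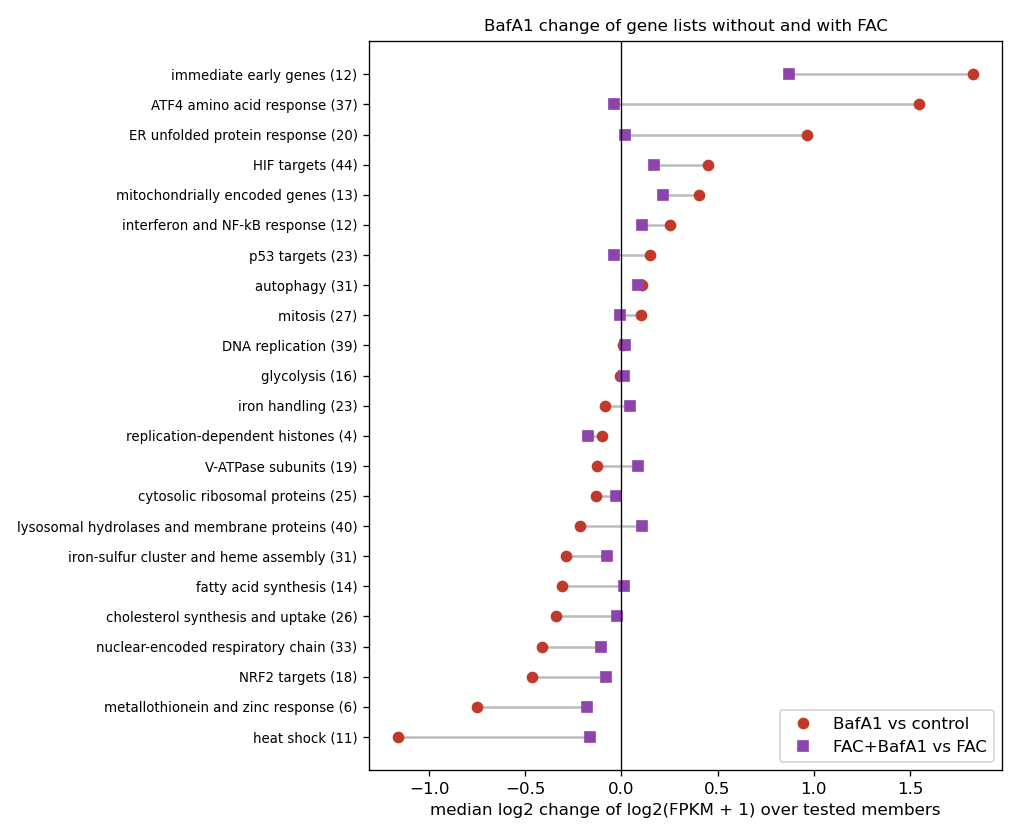
Median log2 change of each gene list after BafA1, without FAC (circles) and with FAC (squares), with the number of tested members in parentheses. The ATF4 amino acid response lies at 1.55 and -0.04, the immediate early genes at 1.83 and 0.87.

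The comparison of FAC with control asked what added iron did by itself. TFRC fell from 58.3 ± 0.991 to 10.2 ± 1.29 FPKM (SD, n = 3), 5.69-fold (log2 -2.40 ± 0.06, SE; limma adjusted p = 6.71e-12). HMOX1 rose from 21.2 ± 1.42 to 40.3 ± 3.81 FPKM (adjusted p = 5.79e-07), FTL by 0.30 ± 0.04 log2 units (adjusted p = 0.000102) and NCOA4 by 0.26 ± 0.03 (adjusted p = 8.69e-06). Cholesterol genes rose: HMGCS1 went from 51.3 ± 0.860 to 82.7 ± 0.157 FPKM (log2 0.68 ± 0.03, adjusted p = 1.20e-09), and INSIG1, a sterol-regulated ER anchor protein, from 59.0 ± 2.39 to 106 ± 1.57 FPKM (adjusted p = 5.65e-10). Of 26 genes in that list 17 were higher, or 21 adjusted over the list alone (median 0.31, camera adjusted p = 1.99e-14, and 0.00199 with an estimated correlation).

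Fatty acid synthesis genes were higher with FAC in 8 of 14 cases, or 9 adjusted over the list alone (median 0.19, camera adjusted p = 5.81e-05, and 0.0158 with an estimated correlation), among them ELOVL6, a fatty acid elongase (0.34 ± 0.04, adjusted p = 2.79e-05). NRF2 targets were higher in 4 of 18, or 7 adjusted over the list alone (median 0.09, adjusted p = 0.000365, and 0.0183 with an estimated correlation), among them SLC7A11, the cystine importer (0.28 ± 0.05, adjusted p = 0.00241). The ATF4 genes had a median of 0.06 (adjusted p = 0.0176, and 0.0865 with an estimated correlation). The metallothionein and zinc response did not pass as a list, with 1 of 6 genes higher and 4 lower (median -0.48, adjusted p = 0.0617, and 0.134 with an estimated correlation). It passed in some alternatives, such as without FAC replicate 2 (adjusted p = 0.0464) and with a mean of at least 1 FPKM on both sides of FAC (adjusted p = 0.0098). In it MT2A, a metal-binding metallothionein, was at -0.61 (adjusted p = 0.000239), MT1X at -0.53 (adjusted p = 0.000393) and SLC30A1, the zinc exporter, at -0.43 log2 units (adjusted p = 0.000583). SLC39A10, a zinc importer, rose from 24.3 ± 0.489 to 36.1 ± 0.188 FPKM (adjusted p = 4.92e-08). The iron handling list had a median of 0.01 and a mean of -0.07, which differ in sign, with 3 higher and 2 lower, or 3 and 3 adjusted over the list alone (adjusted p = 0.904). HIF targets had a median of -0.01 (adjusted p = 0.964). With at least 1 FPKM on both sides of FAC, a setting chosen after the data were seen, further lists passed camera with the preset correlation. They were autophagy (median 0.05, adjusted p = 0.0036), lysosomal genes (0.04, 0.018), the ER unfolded protein response (0.03, 0.0223), cytosolic ribosomal proteins (0.03, 0.0325) and mitochondrially encoded genes (-0.13, 0.0247). An estimated correlation was not tried there.

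SLC11A2 was at -0.26 ± 0.06 (adjusted p = 0.0119), a call lost without control replicate 1 (adjusted p = 0.0621), FAC replicate 1 (adjusted p = 0.0634), FAC replicate 2 (adjusted p = 0.052) or with the 2 groups fitted alone (adjusted p = 0.061). SQSTM1 was at 0.16 ± 0.03 (adjusted p = 0.00777), a call lost with the 2 groups fitted alone (adjusted p = 0.0694). FTH1 (-0.12, adjusted p = 0.067) did not pass, but did without control replicate 3 (adjusted p = 0.0256) or BafA1 replicate 3 (adjusted p = 0.0281) and with array weights (adjusted p = 0.0368). ASNS (0.08, adjusted p = 0.176) did not pass, but did without control replicate 1 (adjusted p = 0.0219). NDRG1 (-0.19, adjusted p = 0.156) and VEGFA (0.09, adjusted p = 0.738) did not pass.

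Most of the large differences between FAC and control lay in non-coding gene entries, the kind that made up most of those at 0 on one side of FAC. Of 1308 called genes (646 higher, 662 lower), 1049 changed by at least 1 log2 unit; 976 of these were non-coding, 46.2% of the 2113 non-coding genes tested, and 73 were coding, 0.631% of 11569. The number of calls depended on the treatment of low values: it was 4486 with no filter and 402 at a mean of at least 5 FPKM. It was 151 for genes with at least 1 FPKM on both sides of FAC, a setting chosen after the data were seen. Among 2634 isolated coding genes 50 were called, 3 of them at least 1 log2 unit in size. The largest increases were NPIPA9, listed at 0 without FAC and at 40.4 to 46.6 FPKM with FAC, a Y RNA entry (ENSG00000200121), a 5.8S ribosomal RNA entry, ZZZ3 (1.26 to 2.45 and 32.2 to 38.4 FPKM) and 1 of 2 entries named PINX1 (ENSG00000254093, 0 to 0.15 without FAC and 22.4 to 26.3 with FAC). The other PINX1 entry (ENSG00000258724), which overlaps the same locus, was among the largest decreases (20.3 to 26.9 without FAC and 0 to 0.16 with FAC), as were 4 Y RNA entries listed at 0 with FAC. Such a pair was not seen among the 627 genes at 0 on one side. By GENCODE positions, 0 of the 304 at 0 without FAC overlapped one of the 323 at 0 with FAC. No fold is given for these entries.

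The comparison of FAC+BafA1 with BafA1 asked what iron changed in cells with blocked lysosomal acidification. ASNS was at 423 ± 4.32 FPKM in BafA1 and 127 ± 3.20 in FAC+BafA1 (SD, n = 3; log2 -1.73 ± 0.03, SE; limma adjusted p = 2.71e-13). NDRG1 was at 76.5 ± 5.95 and 32.8 ± 1.49 (adjusted p = 1.41e-08) and VEGFA at 42.8 ± 2.85 and 17.0 ± 1.75 (adjusted p = 8.65e-08), both lower with FAC. HMGCS1 rose from 53.04 ± 1.44 to 87.6 ± 1.97 FPKM (adjusted p = 5.21e-10). TFRC was at 130.2 ± 3.05 and 122 ± 3.03 FPKM (log2 -0.09 ± 0.06, adjusted p = 0.222), so the 5.69-fold difference seen without BafA1 was not found (interaction 2.32). TFRC was called lower only under quantile normalization (adjusted p = 0.0372), without FAC replicate 3 (adjusted p = 0.0224) and with the 2 groups fitted alone (adjusted p = 0.0364).

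FTH1 rose by 0.26 ± 0.04 (adjusted p = 4.16e-05) and FTL by 0.26 ± 0.04 log2 units (adjusted p = 9.12e-05), the latter not under quantile normalization (adjusted p = 0.116). SLC11A2 (0.03, adjusted p = 0.686) and SQSTM1 (0.01, adjusted p = 0.783) did not pass. Of the ATF4 genes 36 of 37 were lower (median -1.22, camera adjusted p = 1.14e-20, and 0.000609 with an estimated correlation). Of the ER unfolded protein response 18 of 20 were lower (median -0.85, adjusted p = 4.77e-09, and 0.00253 with an estimated correlation), and of the immediate early genes 11 of 12 (median -1.13, adjusted p = 1.57e-06, and 0.0474 with an estimated correlation). HIF targets had 23 of 44 lower and 8 higher, or 24 and 8 adjusted over the list alone (median -0.26, adjusted p = 0.000664, and 0.0175 with an estimated correlation). Cholesterol genes were higher in 25 of 26 (median 0.73, adjusted p = 4.24e-08, and 0.01 with an estimated correlation). Lysosomal genes were higher in 34 of 40 (median 0.41, adjusted p = 1.83e-05, and 0.0193 with an estimated correlation) and heat shock genes in 10 of 11 (median 0.97, adjusted p = 4.51e-05, and 0.0242 with an estimated correlation). Further lists passed with the preset correlation but not with an estimated one: the respiratory chain (median 0.33, adjusted p = 8.88e-06 and 0.113), fatty acid synthesis (median 0.37, adjusted p = 0.0251 and 0.0768), mitosis (median -0.10, adjusted p = 0.026 and 0.0679), mitochondrially encoded genes (median -0.38, adjusted p = 0.0326 and 0.641) and cytosolic ribosomal proteins (median 0.13, adjusted p = 0.0257 and 0.641). The mitochondrial call was also lost without BafA1 replicate 1 (0.0566), BafA1 replicate 3 (0.066) or FAC+BafA1 replicate 3 (0.0884). The ribosomal call was also lost with median-of-ratios scaling (adjusted p = 0.192), quantile normalization (0.775) and no trend (0.0606), and without BafA1 replicate 3 (0.0521).

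The fit called 9294 genes, 5314 higher and 3980 lower with FAC. The larger number of higher genes (57.2% of calls) was not found with median-of-ratios scaling (50.1%) and was smaller under quantile normalization (52.6%). Of 1351 that changed by at least 1 log2 unit, 1020 were non-coding and 331 coding. The rule again named NPIPA9, both PINX1 entries, Y RNA entries and the 5.8S entry, and added 7SK, a regulatory RNA (7.03 to 15.05 FPKM with FAC), and OR4M2B, an olfactory receptor entry (16.3 to 21.3 FPKM without FAC), each listed at 0 on the other side.

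The comparison of FAC+BafA1 with control asked how far cells given both treatments lay from untreated cells. TFRC rose from 58.3 ± 0.991 to 122 ± 3.03 FPKM (log2 1.06 ± 0.06, SE; limma adjusted p = 2.40e-08). FTL rose by 0.51 ± 0.04 (adjusted p = 4.38e-07), HMGCS1 by 0.76 ± 0.03 (adjusted p = 3.71e-10) and NDRG1 by 0.76 ± 0.07 (adjusted p = 2.19e-06). SQSTM1 rose by 0.65 ± 0.03 (adjusted p = 8.98e-09), VEGFA by 0.42 ± 0.09 (adjusted p = 0.00338) and SLC11A2 by 0.25 ± 0.06 log2 units (adjusted p = 0.00715). ASNS was at -0.18 ± 0.03 (adjusted p = 0.000806). FTH1 was at 0.12 ± 0.04 (adjusted p = 0.0209), a call lost without control replicate 3 (adjusted p = 0.078), FAC+BafA1 replicate 1 (adjusted p = 0.0679) or FAC+BafA1 replicate 2 (adjusted p = 0.0769), under quantile normalization (adjusted p = 0.0506) and with no intensity trend (adjusted p = 0.0553).

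Cholesterol genes were higher in 19 of 26, or 20 adjusted over the list alone (median 0.23, camera adjusted p = 2.01e-07, and 0.0117 with an estimated correlation). Lysosomal genes were higher in 17 of 40 (median 0.11, adjusted p = 0.000694, and 0.0472 with an estimated correlation). Autophagy genes were higher in 15 of 31 (median 0.14, adjusted p = 0.000473, and 0.0175 with an estimated correlation) and immediate early genes in 9 of 12 (median 0.89, adjusted p = 1.29e-07, and 0.0336 with an estimated correlation). HIF targets were higher in 19 of 44 and lower in 6, or 22 and 6 adjusted over the list alone (median 0.15, adjusted p = 0.00629, and 0.028 with an estimated correlation). Lower lists were the respiratory chain, with 17 of 33 lower, or 19 adjusted over the list alone (median -0.12, adjusted p = 0.000424, and 0.195 with an estimated correlation), and heat shock, with 7 of 11 lower and 0 higher, or 7 and 1 adjusted over the list alone (median -0.16, adjusted p = 0.0022, and 0.0629 with an estimated correlation). Fatty acid synthesis (median 0.20, adjusted p = 0.0337 and 0.0898) and V-ATPase subunits (median 0.07, adjusted p = 0.0257 and 0.146) also passed with the preset correlation but not with an estimated one, and the V-ATPase call was lost without FAC+BafA1 replicate 3 (adjusted p = 0.0567). The fit called 4498 genes, 2220 higher and 2278 lower; 986 of the 1111 that changed by at least 1 log2 unit were non-coding. With no filter on low values 7643 were called. The largest changes were again in NPIPA9, PINX1 and Y RNA entries.

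On GRCh38, with GENCODE release 44, the genes followed through every comparison were TFRC (ENSG00000072274) on chromosome 3 from 196012511 to 196082153, SLC11A2 (ENSG00000110911) on chromosome 12 from 50979401 to 51028566, FTH1 (ENSG00000167996) on chromosome 11 from 61959718 to 61967634, FTL (ENSG00000087086) on chromosome 19 from 48965309 to 48966879 and SQSTM1 (ENSG00000161011) on chromosome 5 from 179806398 to 179838078. Further genes were NDRG1 (ENSG00000104419) on chromosome 8 from 133237175 to 133302022, VEGFA (ENSG00000112715) on chromosome 6 from 43770184 to 43786487, ASNS (ENSG00000070669) on chromosome 7 from 97851677 to 97872542 and HMGCS1 (ENSG00000112972) on chromosome 5 from 43287470 to 43313512. Of the other genes discussed, the annotation places EGR1 (ENSG00000120738) on chromosome 5 from 138465479 to 138469303, ATF3 (ENSG00000162772) on chromosome 1 from 212565334 to 212620777, HSPA1B (ENSG00000204388) on chromosome 6 from 31827738 to 31830254, HSPA1A (ENSG00000204389) on chromosome 6 from 31815543 to 31817946 and HMOX1 (ENSG00000100292) on chromosome 22 from 35380361 to 35394214. It also places HSPA5 (ENSG00000044574) on chromosome 9 from 125234853 to 125241382, XBP1 (ENSG00000100219) on chromosome 22 from 28794555 to 28800597 and NPIPA9 (ENSG00000183889) on chromosome 16 from 16317444 to 16350590, and the PINX1 entries on chromosome 8 from 10764961 to 10839884 (ENSG00000254093) and from 10725399 to 10839847 (ENSG00000258724).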

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

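The tests of gene models, depth, regression after selection, gene entries, common compression and read assignment were chosen only after the results were seen; the regroupings of the libraries were planned.

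The BafA1 response differed between cells with and without FAC by the limma interaction test, which called 6850 genes, and 6440 of 9180 BafA1 calls were smaller with FAC. Of 2634 genes called for BafA1 with FAC, 1325 had a larger change without FAC and 444 a smaller one. Regression towards 0 after selection is argued against for large changes. Genes were chosen in 2 libraries per group for a call and a change of at least 1 log2 unit (690 to 766 genes). The change with FAC came from those 2 libraries per group, and the BafA1 change without FAC from the left-out control and BafA1 libraries. The ratio of their medians was at most 0.235, where 1 would mean no loss. Smaller changes were not tested in this way. Gene entries that the libraries assign differently are argued against by isolated coding genes, of which 71.6% changed less, against 70.2% of all calls. One common compression of changes, acting alone, would give lists equal ratios. In the 3 lists with a median BafA1 change of at least 1 log2 unit in size, the ratios spread over 0.496. They went from -0.03 in the ATF4 list through 0.21 in heat shock to 0.46 in the immediate early genes (permutation p = 0.00014, 100000 permutations of list membership). The permutations take genes as independent, so this p does not measure the spread between libraries. The ratios argue against a compression acting alone, while a compression together with changes particular to a list stays open. In 100 regroupings of the 12 libraries, the real one included, 1 gave as many interactions (the highest other 1290) and 1 as many smaller changes (the highest other 1085). The regroupings mix libraries that differ in FAC and in BafA1, so both treatments add to the spread within the groups formed. They are therefore no picture of data that lack only the interaction, and they cannot exclude chance for it. Whether iron supply or a weaker action of BafA1 in the presence of FAC accounts for the smaller response was not tested, and both stay open. After BafA1, TFRC reached 122 FPKM with FAC and 130.2 without. The share of low values near whole fragments also parted the libraries by FAC (65.2% to 69.4% without, 83.7% to 88.6% with). A processing difference other than those weighed above cannot be told apart from FAC and stays open too.

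The 627 genes at 0 on one side of FAC were non-coding or overlapped another gene in 99.8% of cases, against 77.0% of 13355 reference genes, as gene models or read assignment that differ between the libraries with and without FAC would give. However, 0 of the 304 at 0 without FAC overlapped in position one of the 323 at 0 with FAC. A swap between overlapping entries was thus not seen among them. Depth is argued against, since 51.5% of them were at 0 on the deeper side (mean depth 37.6 against 36.4 M fragments). Isolated coding genes made up 0.159% of them, against 19.3% of the 13682 genes tested. This is the same count seen from the other side and no second test. Entries at exactly 0 in 6 libraries may be mostly non-coding whatever the cause. The share therefore cannot decide whether expression of these genes changed with FAC. Whether and where processing differed is not given in the sources used here, and for these entries it cannot be told apart from FAC treatment.

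Lower TFRC, lower ID1, ID2 and ID3, and a higher cholesterol list with FAC were weighed against read assignment that differs between the libraries with and without FAC, which would give the same offset with and without BafA1. For TFRC the FAC change differed by 2.32 log2 units between them, and for 3 of the 3 ID genes it differed by more than 3 standard errors. A constant offset together with a BafA1 response that differs with FAC would give such a difference too. The interaction test called such responses in 6850 of 13682 genes. This test therefore cannot decide whether the FAC changes without BafA1 come from read assignment. For the cholesterol list, 0 of 10000 random coding lists of the same size and expression had a median FAC change as large (real 0.31, highest random 0.06). That comparison takes up a shift that camera had already found. It shows that the list moved more than other coding genes, and does not ask whether the offset was the same with and without BafA1. For HMGCS1 alone the FAC change was 0.68 without and 0.71 with BafA1, so read assignment stays open for this gene as well. An effect of iron on these genes stays a hypothesis, found and tested on the same data.

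Gene lists whose BafA1 response differed with FAC had these median log2 interactions: -1.25 for the ATF4 amino acid response, -1.06 for immediate early genes, -0.90 for the ER unfolded protein response, -0.25 for HIF targets, 0.88 for heat shock, 0.40 for lysosomal genes, 0.34 for cholesterol genes, 0.345 for the nuclear-encoded respiratory chain, 0.24 for iron-sulfur cluster and heme assembly and -0.087 for mitosis. The respiratory chain (adjusted p = 0.087), iron-sulfur and heme (0.0808) and mitosis (0.0649) calls were lost with an estimated correlation. The iron-sulfur and heme call was also lost with median-of-ratios scaling (adjusted p = 0.0616), without BafA1 replicate 3 (adjusted p = 0.0521), without FAC+BafA1 replicate 3 (adjusted p = 0.0536) and at a mean of at least 5 FPKM (adjusted p = 0.0563). Over all lists and comparisons 58 shifts were called, and 7 of 100 regroupings, the real one included, gave as many (the highest other 64). The regroupings mix libraries that differ in FAC and in BafA1, so the groups formed can carry treatment effects. They therefore cannot decide whether chance alone would give such a total, and chance is not excluded for it.

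Single genes whose BafA1 response differed with FAC by the interaction test included stress and growth-signal genes with negative log2 interactions: EGR1 -3.73, FOS -3.59, ARC -2.94, CTH -2.74, ATF3 -2.53, SESN2 -2.20, ASNS -1.81, DUSP1 -1.47 and MYC -1.13. In the ER unfolded protein response they were -2.44 for HERPUD1, -2.38 for DNAJB9, -1.72 for HSPA5 and -1.47 for XBP1, and among HIF targets -1.88 for STC2, -1.79 for DDIT4, -1.39 for HK2, -1.37 for VEGFA, -1.01 for NDRG1 and -0.99 for BHLHE40. Negative values were also found for NCOA4 (-0.75), SLC39A14 (-0.51) and SQSTM1 (-0.15), the last lost without control replicate 3, FAC replicate 1, FAC replicate 2, FAC+BafA1 replicate 2 or FAC+BafA1 replicate 3 (adjusted p 0.0527 to 0.061). MIR25, a microRNA entry inside another gene, was at -4.04, lost without control replicate 2 or 3, BafA1 replicate 1 or 3, FAC replicate 2, or FAC+BafA1 replicate 1 or 2 (adjusted p 0.0896 to 0.103), and with a replicate block (0.0541), no trend (0.06) or a pseudocount of 0.1 (0.061).

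Positive interactions were 2.32 for TFRC, 2.42 for ID3, 2.27 for HSPA1B, 2.17 for HSPA1A, 1.42 for HSPA8, 1.05 for HSPE1, 0.88 for DNAJB1 and 2.93 for the microRNA entry MIR3661. In iron handling they were 0.82 for STEAP3, 0.38 for FTH1 and 0.29 for SLC11A2, the last lost with median-of-ratios scaling (adjusted p = 0.0574). Cholesterol genes gave 0.65 for SQLE, 0.63 for NSDHL and 0.59 for EBP. Lysosomal genes gave 0.92 for PPT1, 0.81 for CTSB and 0.68 for CD63, and respiratory chain genes 1.24 for ATP5MC1, 0.78 for COX6B1, 0.73 for COX7B and 0.65 for NDUFB10.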

How the results depend on the processing

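The settings with isolated coding genes only and with at least 1 FPKM on both sides of FAC were chosen only after the data were seen. Of 404 results for genes that the naming rule took, 366 kept their direction and their side of the threshold under every alternative run, 23 lost a call under at least 1 alternative, 15 gained one and 0 reversed. Of 138 list results, 66 kept both, 22 lost a call, 49 gained one and 2 reversed (1 result counts under more than one heading): the cytosolic ribosomal proteins for BafA1 with control had a median of 0 under quantile normalization (adjusted p = 0.964), and iron handling for FAC with control had a median of 0.013 with fry in the direction opposite to camera (adjusted p = 0.00903); the cause was not tested. The 58 called list shifts became 36 with an estimated correlation and 102 with fry, which does not compare a list with other genes.

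Gene counts stayed within 1.5 times the reported ones except as follows. With isolated coding genes only, which tests fewer genes, 1993 were called for BafA1 with control, 34 for FAC with control, 1869 for FAC+BafA1 with BafA1, 672 for FAC+BafA1 with FAC, 791 for FAC+BafA1 with control and 1567 for the interaction. With a minimum size of 1 log2 unit, which by construction calls fewer genes, 680, 1351, 53, 1111 and 365 remained for BafA1 with control, FAC+BafA1 with BafA1, FAC+BafA1 with FAC, FAC+BafA1 with control and the interaction. FAC with control gave 4486 calls with no filter, 402 at a mean of at least 5 FPKM and 151 with at least 1 FPKM on both sides, and FAC+BafA1 with control gave 7643 with no filter; the cause was not tested. The share of BafA1 calls lessened with FAC was 60.8% with no filter; this cause was not tested either. Of the calls, 4039 of 9180 were higher for BafA1 with control, 5314 of 9294 for FAC+BafA1 with BafA1 and 4032 of 6850 for the interaction; these shares became 50.4%, 50.1% and 49.3% with median-of-ratios scaling, so the excess of one direction depends on the scaling.

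Leaving out each library in turn gave 8643 to 9199 calls for BafA1 with control, 1239 to 1329 for FAC with control, 8683 to 9376 for FAC+BafA1 with BafA1, 1840 to 2646 for FAC+BafA1 with FAC, 3683 to 4550 for FAC+BafA1 with control and 6371 to 6615 for the interaction, with 66.2% to 70.9% of BafA1 calls lessened and 55 to 64 list shifts. With the replicate number as a block, the counts in the same order were 9082, 1298, 9212, 2366, 4287 and 6702, with 69.6% lessened and 59 list shifts; 3 calls of named genes were lost and 2 gained. Libraries with the same replicate number in different groups had residual correlations across genes of -0.074 to 0.138 (18 pairs), against -0.15 to 0.116 for different numbers (36 pairs), and 5 of 12 libraries were closest to those of their own number. No effect shared by libraries of one number was thus seen. Whether they were handled together cannot be told from these values. Depth near 37 M fragments and values rounded to 2 decimals limit what can be said of genes at a few hundredths of an FPKM, such as CA9.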

Other observations

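The tests on ID1, ID2 and ID3, and the genes named here, were chosen only after their values were seen; the splits of the libraries were planned.

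The 8 genes of this paragraph were taken up for what is known of BMP signalling, and no list of such genes was tested. Without BafA1 all 8 were lower with FAC. They were picked with these values known and other genes of the pathway were not counted, so this tally is no test of the pathway. ID3, an inhibitor of basic helix-loop-helix transcription factors, went from 60.4 ± 2.81 FPKM in control to 4.06 ± 0.553 in FAC (SD, n = 3; log2 -3.60 ± 0.09, SE; limma adjusted p = 7.14e-12), ID2 from 113 ± 1.89 to 24.8 ± 1.63 (log2 -2.14 ± 0.05, adjusted p = 5.36e-12) and ID1 from 6.17 ± 0.959 to 0.680 ± 0.226 (log2 -2.09 ± 0.12, adjusted p = 2.93e-08). ID4 was at -0.72 log2 units (adjusted p = 2.08e-07). SMAD6 and SMAD7, inhibitors that the pathway induces against itself, were at -1.24 (adjusted p = 6.85e-06) and -0.98 (adjusted p = 7.14e-06), SMAD9, a signal transducer, at -0.74 (adjusted p = 2.14e-07) and BAMBI, a decoy receptor, at -0.49 (adjusted p = 0.000511). With BafA1 on both sides, the FAC change was -1.19 for ID3 (adjusted p = 2.46e-07), -1.47 for ID2 (1.71e-10), -0.88 for ID1 (4.62e-05), -1.33 for ID4 (3.07e-10), -0.33 for SMAD7 (0.0105) and -0.43 for SMAD9 (1.55e-05). SMAD6 did not pass there (0.00, adjusted p = 0.979) and BAMBI was higher with FAC (0.27, adjusted p = 0.0075). After BafA1 without FAC, ID3 was at 16.6 ± 1.98 FPKM and SMAD6 at 1.54 ± 0.131, against 5.78 ± 0.351 in control, while ID4 rose from 24.6 ± 0.781 to 41.5 ± 0.815. The 5 genes other than ID1, ID2 and ID3 were not part of a test of read assignment.

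Of the 9180 BafA1 calls, 23 were larger with FAC by the interaction test. Besides TFRC they included LPCAT1, a phospholipid acyltransferase, at 33.4 FPKM in control, 48.8 in BafA1, 34.3 in FAC and 88.4 in FAC+BafA1 (interaction 0.80 ± 0.07, adjusted p = 1.63e-06). EMILIN2, an extracellular matrix glycoprotein, was at 5.15, 8.98, 1.10 and 4.80 FPKM in the same order. HMOX1 had an interaction of -0.47 (adjusted p = 0.0021), that is a larger decrease after BafA1 with FAC.

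In comparisons of a pair of groups, 3 libraries against 3 make 10 splits, too few for a share under 0.05. The real split alone, 1 of 10, gave as many calls in each: 9180 for BafA1 with control (highest other 1), 1308 for FAC with control (highest other 0), 9294 for FAC+BafA1 with BafA1 (highest other 0), 2634 for FAC+BafA1 with FAC (highest other 1) and 4498 for FAC+BafA1 with control (highest other 0).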
